A study of Mus musculus with 6 samples.

How the data were processed

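ATAC-seq libraries came from CD8+ T cells of wild-type mice, taken from pancreas, spleen and lymph nodes per the labels, and kept for 48 hours in T cell medium with palmitate (100 µM, 3 libraries) or as control (3 libraries). Per the labels, 50000 cells purified by FACS were lysed for each library, and the tagmented DNA was isolated on SPRI beads, amplified by PCR and size-selected. The submitters' notes name Trim Galore 0.6.10, Bowtie2 2.5.1, Picard 2.23.8, MACS2 2.2.8 and edgeR 3.40.2 and the genome build mm10. The shift of reads to the Tn5 cut, the building of the consensus regions and the counting of reads are not given in the sources used here.

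The count matrix as deposited by the authors holds raw whole-number counts of 6 libraries in 24605 regions, 141 to 3075 bp wide (median 443 bp), on chromosomes 1 to 19 and X. All its columns were used. Each peak list as deposited by the authors holds 1 library's peaks after their own filtering, with a score from the authors' peak calling. These peak scores are the authors' own and were used as given. Every region of the matrix lay in at least 2 of the 6 peak lists and 14761 lay in all 6. Because more peaks were called in control, the matrix selects for regions open in control, and regions in all 6 lists were therefore also examined alone. Coordinates are printed as the matrix gives them, where each region starts 2 bp before the start of a listed peak.

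Depth was 2219136 to 3089230 counts in regions per library, with a median count per region of 46 to 62. The common biological coefficient of variation was 0.0659. In simulated data of this depth and spread, the edgeR test found 6% of regions changed 1.25-fold and 40% of those changed 1.5-fold. It found 72% and 92% of those changed 2-fold and 3-fold (50 regions at each fold change), with 5 false calls among 110. With so few changed regions the adjustment is stricter than in the data, where 5972 were called. These shares therefore do not give the power reached in the data. In 20 simulated draws, camera called a list of 25 regions shifted 1.25-fold in 20, and called 3 of 600 unshifted lists. The simulated regions were independent, the lists random, and no trend on region strength was built in. These draws therefore do not give the rate of false list calls in the data.

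Groups, tests, gene lists, named genes and most alternatives were fixed before the data were examined. Differential accessibility was tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), two-sided, with TMM factors (0.953 to 1.05), the filterByExpr count filter, which left 24316 regions and removed 289, and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use the TMM library sizes. Alternatives were DESeq2 size factors, total counts, upper-quartile factors, no count filter, at least 20 reads in 3 libraries, a false discovery rate of 0.1, glmTreat against 1.5-fold, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom (limma 3.58.1), autosomes only, removal of the top 1% of regions, a replicate block, and each library left out in turn. Trended offsets, a loess curve (span 0.3, pseudocount 0.5 reads) of each library's log count on mean abundance, were also among those fixed. Chosen after the data were seen were regions in all 6 lists, trended offsets with each library left out, with other list settings or on abundance and region width together, the class tests with trended offsets, in regions of all 6 lists or with a library left out, peaks above the median score of all lists, and overlaps with a library left out. The offsets on abundance and width replaced, as the test of background for the trended calls, a comparison with other splits of the libraries, which mix the groups and could not decide.

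Regions were located with a table of 21900 protein-coding genes of GRCm38.p6, the assembly of mm10. The table was used for gene spans without strand, so the planned distance of 1 kb to a transcription start became 1 kb to either end of a protein-coding gene (alternative 2.5 kb), and the classes became gene end, inside gene and intergenic. The 9422 gene-end regions thus include ends of transcription. Class shares of called regions were compared by Fisher's exact test and classes by camera. Motif tests and offsets for GC content were not run, since no genome sequence was used here.

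The 31 gene lists covered T cell effector molecules, activation and costimulation, inhibitory receptors and exhaustion, naive and memory T cells, T cell receptor signalling, metabolism, stress and growth responses, ribosomal proteins as a reference, and markers of other cell types. Each gene was represented by its gene-end region with the highest mean count. Camera with a preset correlation of 0.01 tested 26 lists of at least 3 regions against the 8751 gene-end regions of 10114 genes, two-sided, with Benjamini-Hochberg adjustment over lists, and 5 lists had fewer regions. Alternatives were an estimated correlation, fry, all regions within 50 kb, trended offsets, the replicate block and each library left out. After the data were seen, the calls of each list were also set against those of the gene-end regions nearest in abundance to each member. A shuffle of lower calls among regions was dropped, as it treats neighbouring regions as independent and its limit of 4 regions per gene followed the data. Of 43 oxidative phosphorylation symbols 38 were in the gene table.

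Genes to be named followed a fixed rule. In each direction these were the 10 called regions with the smallest p, 1 per gene, whose palmitate libraries all lay on the same side of all controls, named by the nearest end of a protein-coding gene within 100 kb. The gene-end region of 24 fixed genes was reported whatever its result, with the region of smallest p of the same gene where it passed. Up to 3 members with the smallest p were named for the effector, exhaustion, oxidative phosphorylation, fatty acid oxidation and stress response lists. Some items under this rule are not reported here. The maps of Hk2 and Ifng and the loci with several lower regions were chosen after their values were seen.

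Peak numbers were compared by an exact two-sided permutation test, which cannot go below p = 0.1 for 3 against 3. Overlaps of peak lists (bedtools 2.31.1) were given as the share of peaks overlapping by at least 1 bp, without a test. Figures and tables used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.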

Results

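The series asked how palmitate, a saturated fatty acid abundant in plasma and diet, affects the function of CD8+ T cells, the lymphocytes that kill infected and tumour cells. Wild-type mouse CD8+ T cells were cultured for 48 hours with 100 µM palmitate or without it, and 50000 sorted cells per library entered ATAC-seq. In this assay the Tn5 transposase cuts accessible DNA, so the reads in a region measure how open its chromatin is. There were 3 palmitate and 3 control libraries. The labels number the replicates but do not say whether they came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels give no sequencing batch or date.

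The deposited matrix held raw counts for 24605 regions with a median width of 443 bp. Counts in these regions totalled 2219136, 2855574 and 2852087 in controls 1 to 3, and 2614890, 3089230 and 2720569 in palmitate libraries 1 to 3. The first principal component of the normalised counts carried 52.8% of the variance and separated the groups, with controls between -42.6 and -26.4 and palmitate libraries between 29.1 and 39.4. On this axis control 2 lay nearest to the palmitate libraries. Its counts differed from those of controls 1 and 3 by a chi-square per degree of freedom of 2.06 and 2.03, against 1.2 between controls 1 and 3 and 1.19 to 1.5 between palmitate libraries. Counting noise alone gives a value of about 1. All pairs lay above it, and each library entered as its own replicate.

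**Figure D1:**
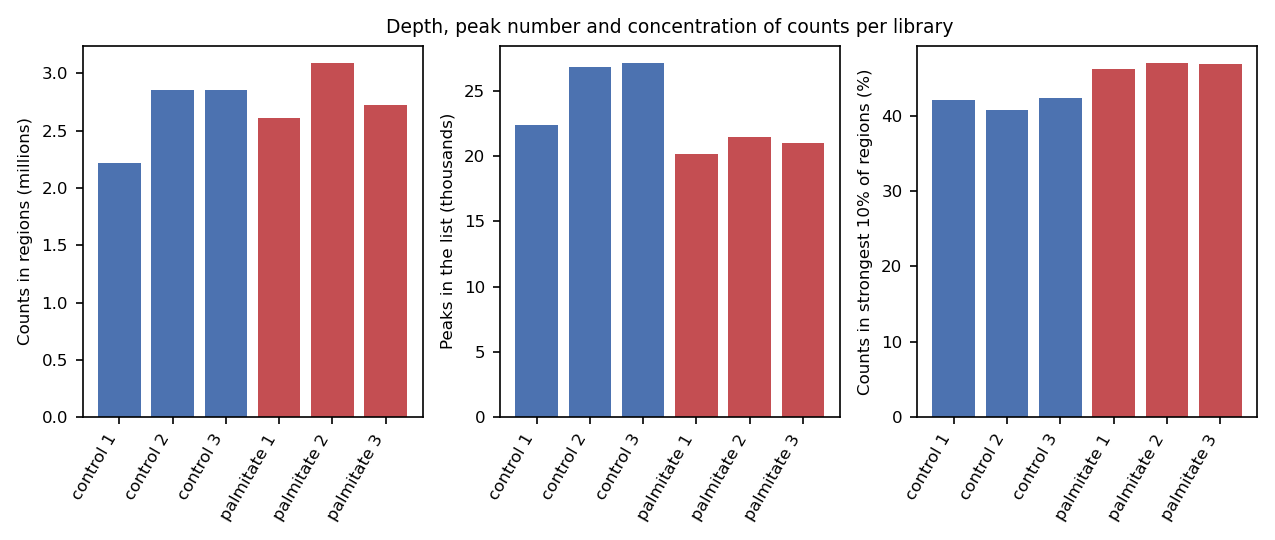
Bars give, for each library, the counts in regions, the number of peaks in its list, and the share of its counts in the strongest 10% of regions in percent, with controls in blue and palmitate in red. Totals ran from 2219136 to 3089230 counts, the palmitate lists held 20201 to 21502 peaks against 22359 to 27122 in control, and the strongest 10% of regions took 46.2% to 46.9% of the counts in palmitate against 40.7% to 42.3% in control.

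Accessibility changed at many loci, in both directions. Among the regions with the smallest p, palmitate lowered an element inside Nfatc2, which encodes an NFAT transcription factor activated by antigen receptor signalling, from 31 ± 9.02 to 8.64 ± 0.681 CPM (counts scaled to library size, mean ± SD, n = 3 per group). It also lowered an element inside Cdk6, a cell cycle kinase of the G1 phase, from 60.2 ± 3.58 to 27.2 ± 3.31 CPM (n = 3). Among the regions that rose, the ends of Prkaca, the catalytic subunit of protein kinase A, and of Sp1, a transcription factor that binds GC boxes, went from 209 ± 5.29 to 306 ± 4.65 CPM and from 718 ± 40.6 to 1006 ± 23.8 CPM (n = 3). With offsets that remove each library's trend of counts on region strength (trended offsets), the log2 fold change fell from 0.55 to 0.24 at Prkaca, which still passed (edgeR adjusted p 0.00882), and from 0.49 to 0.03 at Sp1, which did not (0.716). Of the regions with the smallest p, the 10 lower ones had log2 fold changes from -0.83 to -2.15, and the 10 higher ones from 0.47 to 0.58. The control means were at most 148 CPM in these lower regions and at least 209 CPM in the higher ones. Strong regions reach a small p with a smaller change, so this ranking does not compare the size of losses and gains.

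The lower regions with the smallest p lay mostly away from gene ends, 2 of 10 being within 1 kb of the end of a protein-coding gene. All positions are in mm10, as the count matrix gives them, and a region is named by the nearest gene end, which does not make that gene its target. The element inside Atxn1 (chromosome 13, 45649211 to 45649761) had a log2 fold change of -1.22 ± 0.12 (SE; adjusted p 2.1e-07, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The edgeR adjusted p was 7.15e-07 for the Cdk6 element (chromosome 5, 3460643 to 3461307), with a log2 fold change of -1.14 ± 0.13 (SE), and 2.39e-06 for the Nfatc2 element (chromosome 2, 168491880 to 168492321), with -1.83 ± 0.23 (SE). An intergenic region 8.38 kb from U2af1, a splicing factor, fell by 2.15 on the log2 scale (SE 0.27), from raw counts of 52 to 63 per control library to 10 to 15 per palmitate library. The region 0.638 kb from the end of Rpl3, a ribosomal protein gene, fell by 1.5 (SE 0.16). Further lower regions were at the end of Tspoap1 (-0.97), inside Ubap2 (-1.59), inside Foxn3, a forkhead factor, with Gm51999 as the nearest gene end (-1.13), and 43.5 kb from Copb1, a coatomer subunit (-0.83).

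Of the 10 higher regions, 9 lay at gene ends. The end of Ap2a1, a subunit of the AP-2 clathrin adaptor (chromosome 7, 44929413 to 44930036, also overlapping Tsks), had a log2 fold change of 0.54 ± 0.056 (SE; edgeR adjusted p 2.1e-07). The corresponding values were 0.55 at Prkaca (chromosome 8, 83972620 to 83973047), 0.49 at Sp1 (chromosome 15, 102405381 to 102406834), and 0.58 in an intergenic region 16.6 kb from Chd2, a chromatin remodeller. The ends of Agpat1, an acyltransferase of phospholipid synthesis, and of Ptbp1, a splicing regulator, rose by 0.51 and 0.54. Those of Samd4b, Mxd1, Cnot3 and Grk6 rose by 0.55, 0.52, 0.47 and 0.52.

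Over the whole matrix, 5972 of 24316 tested regions passed a false discovery rate of 0.05 in the edgeR quasi-likelihood test with TMM factors, 2894 higher and 3078 lower in palmitate. The 3 palmitate libraries all lay above, or all below, the 3 controls in 2749 of the higher and 2847 of the lower regions, and the groups did not overlap in 38.9% of all tested regions, where chance gives 10% for 3 against 3. Fold changes followed region strength. The median log2 fold change rose from -0.59 in the weakest decile of regions to 0.27 in the strongest. The weakest decile held 12 of the higher and 608 of the lower regions, and the strongest 1714 and 10.

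The number and direction of the calls depended on the scaling. With trended offsets 1573 regions were called, 559 higher and 1014 lower. Of these, 353 higher and 889 lower were also called with TMM in that direction, and 3 in the opposite one. Of the regions with the smallest p, all 10 lower ones still passed, but 5 of the 10 higher ones did not: Ap2a1 (trended log2 fold change 0.14), Sp1 (0.03), Agpat1 (0.09), Mxd1 (0.17) and Cnot3 (0.07). Higher calls made up 48.5% of calls with TMM, 22.8% with total counts, 35.6% with upper-quartile factors, 35.5% with trended offsets and 61.1% in the DESeq2 Wald test, which called 3160 regions. The median log2 fold change of all regions was -0.05 with TMM and -0.16 with total counts, so every fold change here is relative to that centre. Among the 14761 regions listed in all 6 peak lists, 2838 were called, 1376 higher and 1462 lower. The lower calls numbered 1871 without control 3 and 1919 without palmitate 3, and the trended calls ranged from 503 without control 3 to 2506 without control 2.

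**Figure D2:**
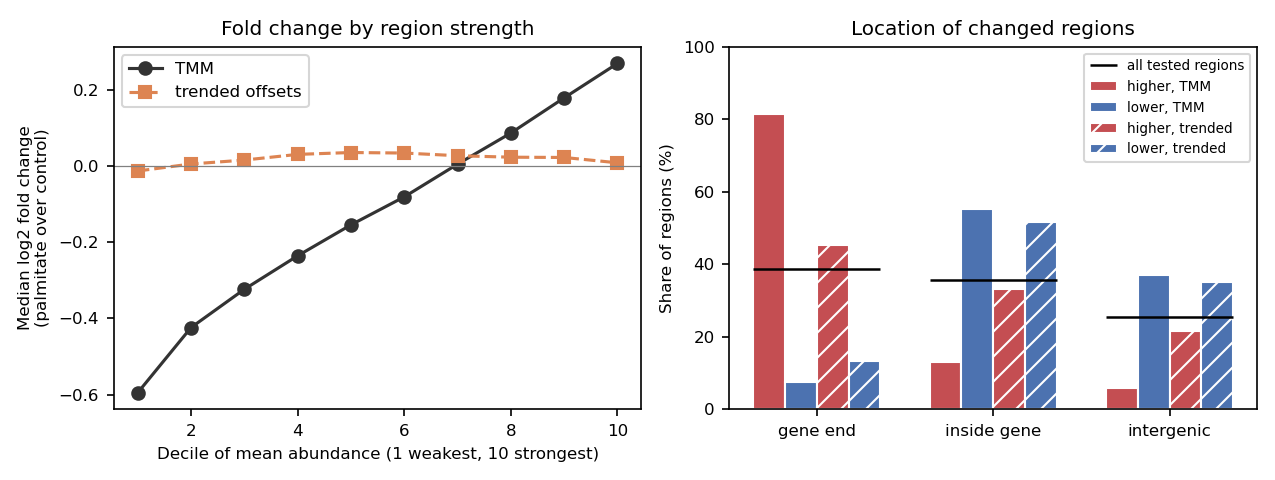
Left, the median log2 fold change of palmitate over control in each decile of mean abundance, with TMM factors (circles) and with trended offsets (squares). It runs from -0.59 to 0.27 with TMM and from -0.01 to 0.04 with trended offsets. Right, the share in percent of higher (red) and lower (blue) regions at gene ends, inside genes and between genes, with TMM (plain) and trended offsets (hatched), and of all tested regions (black line). Gene ends held 81.4% of the higher and 7.54% of the lower regions with TMM, and 45.3% and 13.2% with trended offsets.

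Gains and losses fell in different parts of the genome. Gene ends, defined as regions within 1 kb of either end of a protein-coding gene and so holding most promoters, made up 38.7% of tested regions but 81.4% of the higher ones (2355 regions) and 7.54% of the lower ones (232 regions). Regions inside genes made up 35.8% of tested regions, 12.9% of the higher and 55.4% of the lower ones. Intergenic regions made up 25.6% of tested regions, 5.70% of the higher and 37.1% of the lower ones. With trended offsets regions inside genes made up 33.3% of the higher and 51.8% of the lower ones, and intergenic regions 21.5% and 35%. Inside genes the higher share then did not differ from that of the other regions (odds ratio 0.894, Fisher's exact p 0.228). At Hk2, the hexokinase of activated lymphocytes, the region at the gene end was higher (0.27 ± 0.098 SE), a call kept in only 4 of 16 alternatives, and 3 regions inside the gene were lower, the lowest at -1.46 ± 0.30 (SE; chromosome 6, 82753174 to 82753502). With trended offsets 2 of these 3 passed and the gene end did not. The 2 were this region and the one at 82744467 (edgeR adjusted p 0.0245 and 2.72e-05), and the third, at 82740299, had 0.0934 with a log2 fold change of -0.46, against -0.50 with TMM.

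The odds of lying at a gene end were 53.5 times as high among higher as among lower regions (Fisher's exact test, two-sided, 95% confidence interval 45.4 to 63.4). The odds ratio was 5.42 (4.21 to 7.01, Fisher's exact p 7.92e-44) with trended offsets, chosen after the data were seen. In camera, a test of a set of regions against the rest, gene-end regions were shifted up (adjusted p 3.98e-27, and adjusted p 0.000653 with an estimated correlation). Neighbouring regions are not independent, and gene ends are also the stronger regions, 2078 of the 2432 regions of the strongest decile.

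Of the 25 gene-end regions of endoplasmic reticulum and integrated stress response genes, 15 were higher (16 adjusted over the list alone) and the other 10 did not pass. Gene ends of like strength, those nearest in abundance to each member, would give 14.2 of 25, a comparison chosen after the data were seen. Ddit3, which encodes the stress-induced transcription factor CHOP, went from 201 ± 20.9 to 289 ± 21.4 CPM (n = 3; chromosome 10, 127290346 to 127290981, a region also overlapping Mbd6). Hspa5, the chaperone BiP, went from 255 ± 16.3 to 341 ± 10.5 CPM, and Canx, the chaperone calnexin, from 158 ± 3.42 to 218 ± 7.05 CPM (n = 3). The end of Atf3, another stress-induced factor, had a log2 fold change of 0.33 ± 0.13 (SE) and did not pass (edgeR adjusted p 0.0675). It passed in 2 of 16 alternatives, limma-voom (0.0466) and without control 1 (0.00887). Control 2 had 38.6 CPM there against 71.5 and 63.6 in controls 1 and 3. Without control 2 the edgeR adjusted p was 0.561, and in the DESeq2 Wald test it was 0.454.

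The median log2 fold change of the stress list was 0.29, against 0.15 over all gene-end regions in the list tests. In camera with the preset correlation this list was shifted up (adjusted p 0.00141, Benjamini-Hochberg over 26 lists), with adjusted p = 0.731 with an estimated correlation. With trended offsets, adjusted p was 0.864 and 1 of the 25 regions passed, Ddit3 (log2 fold change 0.22, edgeR adjusted p 0.0248), while Canx and Hspa5 did not (0.0536 and 0.302). At like strength the median log2 fold change was 0.24, against the 0.29 of the list. Of ribosomal protein genes, a reference list, 10 of 32 regions were higher, against 9.4 at like strength, and 0 with trended offsets.

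Of the 13 gene-end regions of effector genes of cytotoxic T cells, 3 were lower, 1 was higher and 9 did not pass (4 lower and 2 higher adjusted over the list alone). Gene ends of like strength would give 0.32 lower and 1.35 higher, and with trended offsets 1 was lower and 0 higher. The end of Gzmb, the granzyme that triggers apoptosis of target cells, went from 42.1 ± 13.2 to 29.3 ± 4.07 CPM (n = 3; chromosome 14, 56262050 to 56262721). Nkg7, a protein of cytotoxic granules, went from 80.0 ± 10.1 to 63.6 ± 9.70 CPM (n = 3; chromosome 7, 43436407 to 43437158). The member that rose was Id2, a transcriptional regulator of effector differentiation, from 76.9 ± 4.37 to 106 ± 11 CPM (n = 3).

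Gzmb had a log2 fold change of -0.51 ± 0.18 (SE; edgeR adjusted p 0.0313), Nkg7 of -0.32 ± 0.11 (SE; 0.0291) and Id2 of 0.46 ± 0.092 (SE; 0.000519). With trended offsets the log2 fold change stayed at -0.51 ± 0.18 (SE) for Gzmb while its adjusted p rose to 0.0785, as fewer regions passed overall. It became -0.47 for Nkg7 (0.00763) and 0.27 ± 0.090 (SE) for Id2 (0.0645). Control 2, the control that stood apart, had 26.9 CPM at Gzmb against 48.8 and 50.7 in controls 1 and 3, and the Gzmb call was lost without control 1, control 3, palmitate 1 or palmitate 2 (edgeR adjusted p 0.129, 0.288, 0.14 and 0.0734), as well as in limma-voom (0.0834) and the DESeq2 Wald test (0.148). Nkg7 was also lost without these libraries (0.143, 0.138, 0.138 and 0.142), with DESeq2 size factors in edgeR (0.0538) and in the DESeq2 Wald test (0.191). An intergenic region 21.9 kb from Gzmb was lower as well (log2 fold change -0.64 ± 0.16 SE, edgeR adjusted p 0.00425; 0.0339 with trended offsets).

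The median log2 fold change of the effector list was -0.25. Camera with the preset correlation shifted it down (adjusted p 0.0441), with adjusted p = 0.731 with an estimated correlation and 0.334 with trended offsets. The adjusted p was 0.0617 without control 1, 0.0877 without control 3 and 0.0909 without palmitate 2. At the ends of Prf1, the pore-forming perforin, and of the cytokine genes Ifng and Tnf, log2 fold changes were -0.31 ± 0.16, -0.55 ± 0.22 and -0.16 ± 0.16 (SE), and at Tbx21, the T-bet transcription factor, -0.25 ± 0.26 (SE). None of these 4 passed (edgeR adjusted p 0.149, 0.0645, 0.506 and 0.514). The Ifng end was lower with total counts (0.0285), with upper-quartile factors (0.0441) and without palmitate 1 (0.0378), and the Prf1 end with total counts (0.0485). Ifng had 3 lower regions outside its span, that with the smallest p 33.7 kb from its end (chromosome 10, 118406939 to 118407305), at 17.7 ± 0.269 CPM in control and 6.92 ± 2.17 in palmitate (n = 3; log2 fold change -1.37 ± 0.26 SE, edgeR adjusted p 0.000235). With trended offsets this region passed (0.0081) and the other 2 did not (0.236 and 0.468).

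**Figure D3:**
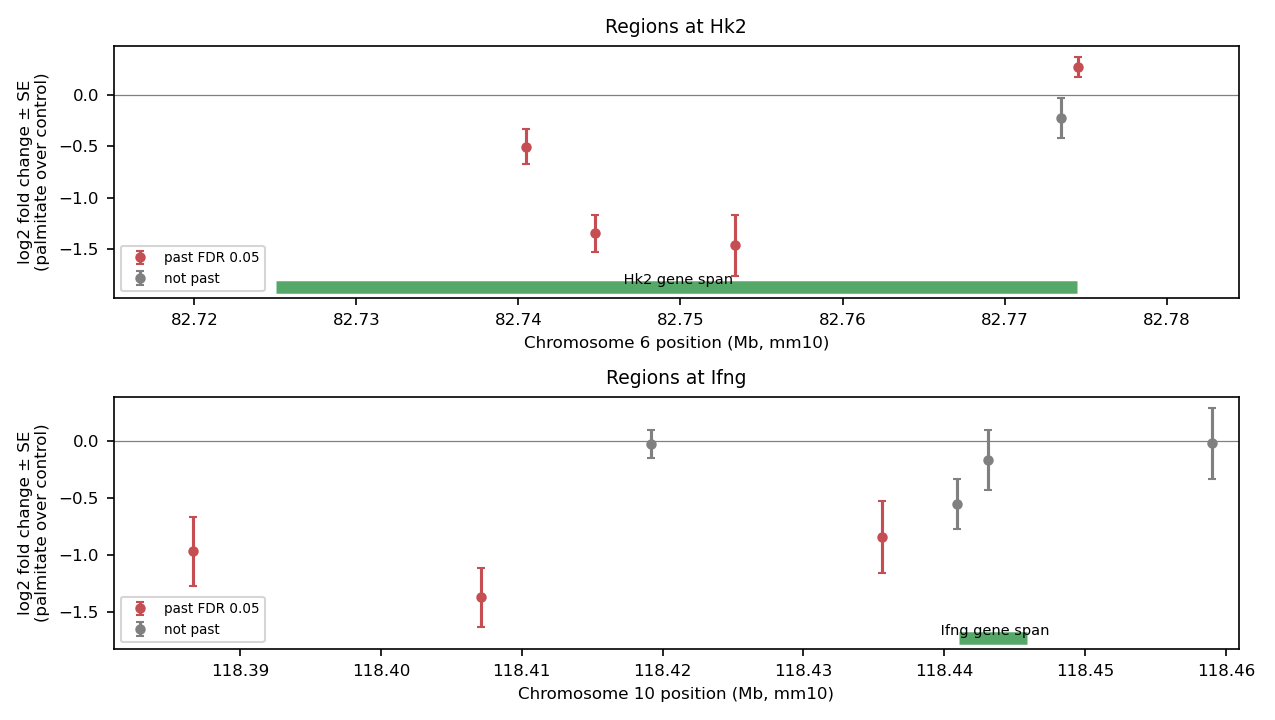
Each point is a region at Hk2 or Ifng, placed by its position in Mb (mm10) and its log2 fold change of palmitate over control, with bars of 1 SE, red where it passed a false discovery rate of 0.05 with TMM factors, and a green bar for the gene span. At Hk2 the region at the gene end stood at 0.27 and the lowest at -1.46, and at Ifng the lowest stood at -1.37.

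Of 16 gene-end regions of inhibitory receptor and exhaustion genes, 0 passed in edgeR, limma-voom or DESeq2. Gene ends of like strength would give 1.9 higher and 0.48 lower. At an unadjusted p below 0.05 in edgeR 3 were higher, while 8892 of all 24316 tested regions were below it in either direction. These 3 were Btla and Lag3, both inhibitory receptors, and Nr4a3, a nuclear receptor induced by antigen, with log2 fold changes of 0.45 ± 0.18, 0.45 ± 0.18 and 0.24 ± 0.099 (SE; edgeR adjusted p 0.0612, 0.0631 and 0.0715). All 3 passed with DESeq2 size factors in edgeR (0.0407 for Btla, 0.0466 for Lag3 and 0.0452 for Nr4a3). Lag3 also passed with a replicate block (0.0446) and without control 1 (0.0103) or palmitate 3 (0.0483). Btla also passed without control 2 (0.0117) and Nr4a3 without palmitate 3 (0.0483). Lag3, Btla and Nr4a3 thus passed in 4, 2 and 2 of 16 alternatives. Control 2 had 19.6 CPM at Lag3 against 38.4 and 30.3 in controls 1 and 3, and without it Lag3 had an edgeR adjusted p of 0.343. Among the 69 regions within 50 kb of this list's genes, 2 were higher and 13 lower with TMM (median log2 fold change -0.11, camera adjusted p 0.0847), and 1 and 3 with trended offsets. Over all tested regions 19.6% of those inside genes, 18.4% of intergenic ones and 2.47% of gene ends were lower with TMM. Pdcd1, the PD-1 receptor, stood at 17.1 ± 3.34 CPM in control and 17.1 ± 2.2 in palmitate (n = 3), and Tox, a regulator of exhaustion, at 40.5 ± 6.12 and 37.7 ± 2.44 CPM (n = 3). Havcr2, the TIM-3 receptor, had 10 to 26 raw counts per library at its end (log2 fold change -0.35 ± 0.33 SE, edgeR adjusted p 0.47). A weak region inside Havcr2 was lower (-0.92 ± 0.29 SE, 0.0177), with 0.241 with trended offsets, and was lost without control 1, control 3 or palmitate 3 (0.0745, 0.0768 and 0.109) and in the DESeq2 Wald test (0.0997).

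Genes of naive and memory T cells had 2 higher of 16 regions (1 adjusted over the list alone), and 0 with trended offsets. Tcf7, the TCF-1 factor of stem-like T cells, had 0.15 ± 0.19 (SE) at its end and Il7r, the IL-7 receptor, -0.36 ± 0.20 (SE), neither past the threshold (edgeR adjusted p 0.6 and 0.185). A region 30.6 kb from Tcf7 was higher (0.35 ± 0.087 SE, 0.00339), with 0.321 with trended offsets and 0.0549 without palmitate 3. Activation and costimulation genes had 6 higher and 1 lower of 18 regions, and T cell receptor signalling genes 4 higher of 21. Gene ends of like strength would give 5.3 higher and 0.32 lower for activation, 3.46 higher for signalling and 2.81 for naive and memory genes. With trended offsets 2 regions of the activation list were lower and 1 of the signalling list higher, and the rest did not pass. Within 50 kb, 11 regions were higher and 21 lower of 111 for activation, and 6 higher and 10 lower of 140 for signalling (edgeR, TMM). With trended offsets these were 3 and 11 for activation, and 3 and 4 for signalling. Of all tested regions inside genes 19.6% were lower with TMM, of intergenic ones 18.4% and of gene ends 2.47%.

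Genes of mitochondrial respiration and fatty acid metabolism rose at some of their ends but as lists did not pass against other gene-end regions. In oxidative phosphorylation 8 of 36 regions were higher, 1 lower and 27 did not pass, where gene ends of like strength would give 7.96 higher. With trended offsets 1 of these 36 was higher, and none in fatty acid oxidation or glycolysis. Cycs, cytochrome c, went from 142 ± 5.09 to 182 ± 5.80 CPM, and Atp5b, a subunit of the ATP synthase, from 134 ± 9.82 to 173 ± 12 CPM (n = 3). Ndufv1, a complex I subunit, went from 99.1 ± 9.48 to 128 ± 10.5 CPM (n = 3). Trended offsets reduced the log2 fold change from 0.36 to 0.10 at Cycs, from 0.37 to 0.12 at Atp5b and from 0.37 to 0.16 at Ndufv1, and none passed (edgeR adjusted p 0.356, 0.373 and 0.247). In fatty acid oxidation 6 of 24 regions were higher (7 adjusted over the list alone, 5.74 at like strength), among them those of the lipid-sensing receptors Ppard and Ppara, with log2 fold changes of 0.40 ± 0.078 and 0.36 ± 0.095 (SE). With trended offsets these were 0.17 and 0.19 and did not pass (0.154 and 0.212).

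Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, went from 37.8 ± 4.64 to 49.9 ± 9.44 CPM (n = 3; chromosome 19, 3323084 to 3323529; edgeR adjusted p 0.0274). Its log2 fold change was 0.41 ± 0.14 (SE), and 0.37 ± 0.14 (SE) with trended offsets, where it did not pass (0.106). The call was also lost with total counts (0.119), upper-quartile factors (0.0609), in the DESeq2 Wald test (0.0913) and without control 2, control 3, palmitate 1 or palmitate 2 (0.0651, 0.0853, 0.144 and 0.127). Ucp2, a mitochondrial carrier, and Tfam, which packages mitochondrial DNA, had log2 fold changes of 0.14 ± 0.12 and 0.13 ± 0.082 (SE) and did not pass (edgeR adjusted p 0.395 and 0.268). In glycolysis 6 of 16 regions were higher (5.3 at like strength). The end of Hk2 was one of them (edgeR adjusted p 0.0443), a call kept in 4 of 16 alternatives. It was lost with trended offsets (0.511), total counts (0.263), upper-quartile factors (0.12), the filter of 20 reads (0.0828), in the DESeq2 Wald test (0.131), limma-voom (0.0541) and both fits with a replicate term, and without control 1, control 2, palmitate 1 or palmitate 2 (0.0946, 0.136, 0.133 and 0.143). The inner Hk2 element at chromosome 6, 82744467 to 82744933, went from 52.8 ± 13.8 to 20.6 ± 5.79 CPM (n = 3; edgeR adjusted p 5.38e-06; 2.72e-05 with trended offsets). Slc2a1, the glucose transporter GLUT1, had 0.09 ± 0.087 (SE; 0.494). Of the 24 genes fixed for reporting, 18 had a tested gene-end region, of which 3 were higher and 1 lower. Pdk4, Plin2, Ppargc1a, Ldha and Atf4 were among the genes without one.

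In further metabolic lists, higher regions numbered 11 of 24 in the tricarboxylic acid cycle, 8 of 25 in mitochondrial translation and biogenesis, 4 of 19 in mitochondrial dynamics and mitophagy, and 10 of 21 in cholesterol synthesis. They numbered 4 of 14 in fatty acid synthesis, 5 of 19 in sphingolipid and ceramide metabolism, and 2 of 17 in fatty acid uptake and storage, where 1 more was lower. For stress and growth lists the numbers were 6 of 20 in the oxidative stress response, 6 of 22 in apoptosis, 6 of 14 in the hypoxia response, 5 of 31 in the cell cycle and 4 of 19 in the interferon response. They were 10 of 20 in the AP-1 and ATF family and 8 of 24 in histone and DNA modifying enzymes. Adjusted over the list alone the numbers became 7 for mitochondrial dynamics, 13 for cholesterol synthesis, 5 for fatty acid synthesis, 8 for hypoxia, 3 for the cell cycle, 11 for AP-1 and ATF and 10 for the modifying enzymes, and stayed as given for the others of this paragraph. Over all tested gene-end regions 25% were higher with TMM. Gene ends of like strength would give 9.38 for the tricarboxylic acid cycle, 8.76 for mitochondrial translation and 4.92 for mitochondrial dynamics. They would give 12.2 for cholesterol synthesis, 4.97 for fatty acid synthesis, 5.2 for sphingolipids and 4.08 for fatty acid uptake. The values were 6.02 for oxidative stress, 6.62 for apoptosis, 5.05 for hypoxia, 10.5 for the cell cycle and 2.32 for interferon. They were 9.7 for AP-1 and ATF and 7.16 for the modifying enzymes. With trended offsets the higher regions were 2 in apoptosis and 1 each in the oxidative stress, cell cycle, AP-1 and ATF and modifying enzyme lists. Lower with trended offsets were 3 regions of mitochondrial dynamics and 1 each of the tricarboxylic acid cycle, cholesterol synthesis, fatty acid uptake and modifying enzyme lists, and the rest did not pass (edgeR). None of these lists, nor the T cell and mitochondrial ones named above other than the stress and effector lists, passed in camera. The lowest adjusted p was 0.0993, for cholesterol synthesis and for the AP-1 and ATF family (median log2 fold changes 0.21 and 0.27). The interferon list had a median of -0.06 (adjusted p 0.171). The sphingolipid list had a median below that of all gene-end regions but a camera direction of up, and the CD4 and regulatory T cell markers the reverse. With trended offsets no list passed (3 at an unadjusted p below 0.05), and none of the higher ends named in the mitochondrial, lipid and glycolysis lists did.

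**Figure D4:**
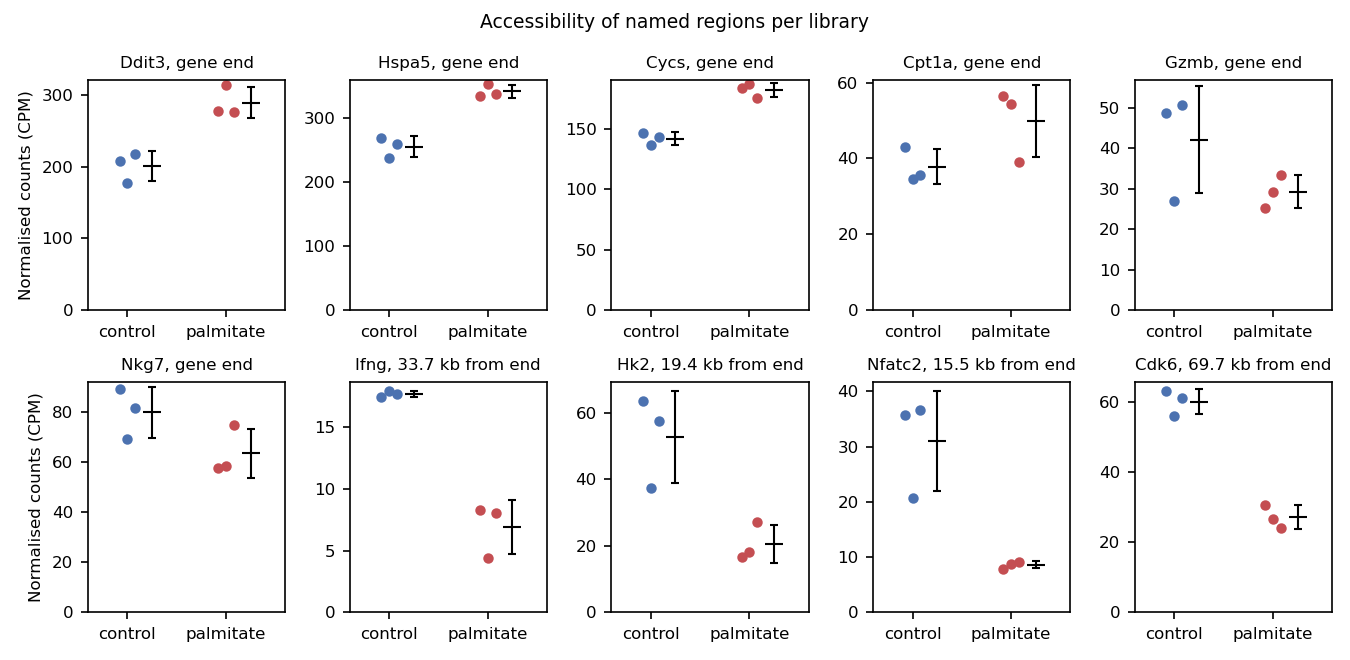
Points are the CPM of each library at 10 named regions, with controls in blue and palmitate in red, and black bars give the mean ± SD (n = 3 per group). Ddit3, Hspa5, Cycs and Cpt1a at gene ends were higher in palmitate with TMM factors, Ddit3 alone of these 4 also with trended offsets. Gzmb and Nkg7 at gene ends and the regions 33.7 kb from Ifng, 19.4 kb inside Hk2, 15.5 kb inside Nfatc2 and 69.7 kb inside Cdk6 were lower. All of these but Gzmb (edgeR adjusted p 0.0785) also passed with trended offsets.

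Markers of other cell types had few accessible gene ends. Among the 3 tested regions of CD4 and regulatory T cell markers 1 was higher, and among the 6 of myeloid and dendritic cell markers 1 was higher (0 and 1 with trended offsets). Within 50 kb the CD4 and regulatory T cell markers had 1 higher and 5 lower of 32 regions, with a median log2 fold change of -0.28, and the effector list 2 higher and 16 lower of 68, with a median of -0.28 (camera adjusted p 0.154 and 0.0488). With trended offsets 0 were higher and 0 lower for the CD4 and regulatory T cell markers (median 0.03), and 0 and 4 for the effector list (median -0.05). For comparison, 19.6% of all tested regions inside genes, 18.4% of intergenic ones and 2.47% of gene ends were lower with TMM. The adjusted p of the effector list became 0.472 with trended offsets and 0.673 with an estimated correlation added, and at gene ends 0.731 with an estimated correlation alone. B cell, natural killer, and erythroid and platelet markers had 2 tested regions each, and pancreatic and stromal markers 1 each, with no call in edgeR, limma-voom or DESeq2. At an unadjusted p below 0.05, 1 natural killer region was higher and 1 lower, and both passed when adjusted over the list alone. Regions within 50 kb of B cell genes stood apart in palmitate 2, where their summed counts were 175 CPM, against 94.2 and 96.3 in palmitate 1 and 3 and 100.1 to 113 in the controls. Without palmitate 2, 4138 regions were called with TMM, 2066 higher and 2072 lower.

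Fewer peaks were called in the palmitate libraries, with 20905 ± 657 per list against 25444 ± 2675 in control (mean ± SD, n = 3). Elements listed in all 3 controls and in no palmitate library numbered 798, and those listed in all 3 palmitate libraries and in no control 59. The difference of -4539 peaks per list had an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries can give. Peaks with a score at or above the median of all lists differed by -592 per list (exact permutation p 0.4, a comparison chosen after the data were seen). Palmitate lists also shared more peaks with each other, 82.4% ± 0.573 (SD over 3 pairs) overlapping by at least 1 bp, than control lists did (78.9% ± 0.815, 3 pairs) or lists of different groups (77.8% ± 1.08, 9 pairs). Pairs share libraries, so no test was made of these shares. They also depend on list length, and control lists were longer. Of palmitate peaks, 86.8% to 90.8% lay in the lists of controls 2 and 3 and 80.3% to 84.1% in that of control 1. In other palmitate lists it was 80.1% to 85.4%, so the shares do not show peak sets particular to a group.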

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

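Chosen after the results were seen were the tests in regions of all 6 peak lists, trended offsets with a library left out or with region width added, trended offsets with an estimated correlation or with regions within 50 kb, classes with trended offsets, regions of all 6 lists or a library left out, peaks above the pooled median score, and overlaps with a library left out. The number of changed regions, 5972 with TMM, stayed within 1.5 times with DESeq2 size factors (6135), total counts (5613), upper-quartile factors (5594), no count filter (6078), a filter of 20 reads (4982), limma-voom (5674), autosomes only (5892), the top 1% of regions removed (5741), a false discovery rate of 0.1 (7874) and each library left out (3997 to 6165). It was 1573 with trended offsets (559 higher, 1014 lower), 1433 with region width added to them (500 higher, 933 lower), 3160 in the DESeq2 Wald test (1229 lower), 258 against a 1.5-fold change (3 higher, 255 lower), and 2838 in regions of all 6 lists (1376 higher, 1462 lower), where fewer regions were tested. Total counts gave 1282 higher regions. Without a library, higher calls ranged from 2066 to 2774 and lower calls from 1871 to 3391. With trended offsets, changed, higher and lower regions numbered 752, 241 and 511 without control 1, 2506, 894 and 1612 without control 2, and 503, 147 and 356 without control 3. They numbered 1054, 370 and 684 without palmitate 1, 783, 214 and 569 without palmitate 2, and 659, 214 and 445 without palmitate 3. Except for the fewer regions tested, the cause was not tested.

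The labels do not say whether libraries with the same replicate number are paired. Deviations from the group mean of libraries with the same number correlated at 4e-04, -0.104 and -0.027. No shared effect was seen, which does not show that the libraries are unpaired. A replicate block gave 5533 changed regions, ended the call at the Hk2 end (0.062) and gave one at the Lag3 end (0.0446), and a replicate block with trended offsets 1411 (466 higher, 945 lower).

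Of the 26 gene lists, 2 passed in camera with TMM, and 1 of 31 with regions within 50 kb. In fry, which tests a list against no change and not against other gene-end regions (median 0.15), 17 passed. With an estimated correlation 0 passed in camera (1 at an unadjusted p below 0.05), with trended offsets 0 (3), with both 0 (0), with trended offsets and regions within 50 kb 0 (3), and with an estimated correlation added to these 0 (0). The replicate block gave 2 lists, and leaving out a library 1 to 2. For the effector list the adjusted p was 0.731 with an estimated correlation, 0.332 in fry (against no change), 0.334 with trended offsets, 0.801 with both trended offsets and an estimated correlation, 0.472 with trended offsets within 50 kb and 0.673 with an estimated correlation added. It ranged from 0.00728 to 0.0909 with a library left out and was 0.0488 within 50 kb, where CD4 and regulatory T cell markers had as low a median (-0.28, unadjusted p 0.0446). For the stress list it was 0.731 with an estimated correlation, 0.0847 within 50 kb, 0.864 with trended offsets and 0.974 with an estimated correlation added. With trended offsets within 50 kb camera turned to down, at 0.917 and, with an estimated correlation, 0.937. It ranged from 0.000125 to 0.00728 with a library left out. The cause was not tested.

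The odds ratio of gene ends among higher against lower regions was 45 at 2.5 kb, 36.8 in regions of all 6 lists, 5.42 with trended offsets, and 42.8 to 73.1 with a library left out. The difference in peaks per list was -592 above the pooled median score, and -6081 to -3700 with a library left out. It was -2289 for the stricter part of each list. That part was cut at each list's own median score, so it keeps the ratio of the full lists and tests nothing further. Overlap within groups exceeded that between groups by 2.85 percentage points, by 3.11 at a reciprocal overlap of 50%, and by 1.84 to 4.44 with a library left out. These shares depend on list length, which differed between the groups. Over 16 alternatives, the 39 called named regions kept the call in 550 of 624 comparisons, lost it in 74 and turned direction in 0, and the other 16 stayed uncalled in 241 of 255 and gained a call in 14. Trended offsets ended 19 of these calls. The 39 include the 10 higher and 10 lower regions picked for the smallest p in the same data, which favours keeping the call. Offsets for GC content, alone or with the block, and motif tests were not run, and chromosomes 1 to 19, X and Y held all peaks. In the simulation 6% of the smallest changes were found. It held far fewer changed regions than were called here, so this share does not give the power in these data.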

Other observations

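All the tests of this part were chosen only after the result was seen, except those of thinning, of the slope on region width and of gene lists in other splits. Several genes had a cluster of lower regions called both with TMM factors and with trended offsets. Etv6, an ETS family repressor, had 5 such regions of 13 (log2 fold changes -2.01 to -0.58), and Thy1, a surface glycoprotein of T cells, 5 of 10 (-1.52 to -0.82). Cdk6 had 4 of 10 (-1.14 to -0.64), Zmiz1, a coregulator of Notch1, 4 of 11 (-1.05 to -0.65), and Nfkb1, the p105 and p50 subunit of NF-kB, 4 of 12 (-1.52 to -0.50), with 1 other region higher with TMM (edgeR, 3 against 3 libraries). These genes were picked for their number of lower regions, and neighbouring regions are not independent, so no test of this clustering is given. Among the 342 higher calls within 100 kb of a gene end the most near one gene was 2. The lower calls there numbered 773, and more calls give more per gene, so this does not compare the directions.

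Strong regions were higher and weak regions lower in palmitate, with a correlation of log2 fold change and mean abundance of 0.548, and of 0.528 after thinning every library to 2219136 counts, which argues against unequal depth. At matched abundance the log2 fold change of the weaker regions fell with width, with a slope of -0.0956 (bootstrap SE 0.0094), as fewer background reads in palmitate could give. Gene ends exceeded other regions by 0.384 without matching and by a mean of 0.147 within abundance deciles, from 0.248 in the weakest to 0.0112 in the strongest. The matched difference was below 0.5 of the unmatched one, and the bootstrap SE of the matched difference minus that part was 0.0064. This argues against a gain at gene ends as the whole cause. With the trend removed 1573 regions were called, where simulated backgrounds at 0.5 and 0.25 of control (correlations of 0.509 and 0.627) gave 395 and 3642 calls with TMM and 1 and 70 with trended offsets. The simulation held no true changes and took a single control background, set from the regions with the fewest counts for their width. Its calls therefore do not bound what a background could give. Offsets on abundance and width together left 1325 of the 1573 called in the same direction, which argues against a background even along the genome as the whole cause, while a background that differs from place to place was not tested.

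The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. Every split but the real one mixes palmitate and control libraries, which widens the spread within its groups. Few changed regions were therefore likely there from the start, and their numbers decide nothing. With TMM 1 of 10 splits gave as many changed regions, the real one with 5972 and the highest other 0 (edgeR; 241 to 1261 at an unadjusted p below 0.05). With trended offsets it was also 1 of 10, with 1573 and 0 (297 to 1691 at an unadjusted p below 0.05 in edgeR). For gene lists, 3 of 10 splits gave as many past the threshold, the real one 2 and the highest other 3.

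Regions near B cell genes were higher in palmitate 2 than in palmitate 1 and 3, by a mean log2 ratio of 0.604 over 9 regions (for one near Pax5 on chromosome 4, 44704379 to 44704757, 62.5 CPM against 26 and 28.8), though not at all of them, as another near Pax5 (8.49 against 8.67 and 12.7) and one near Blk (7.14 against 7.1 and 7.29) show. This was percentile 100 of 10000 random sets of matched abundance, which carry the sampling noise of weak regions, and argues against that noise. An exact binomial test gave p 7.1e-22, but it takes reads as independent, sets separate libraries against counting error alone and was made after these regions were seen to be high. Regions near myeloid genes had a mean log2 ratio of 0.0092 (percentile 66), against such cells. B cells could give the difference, although a sort for CD8+ T cells is meant to remove them. How fully it did so was not tested. No explanation beyond these cell types and noise was tested, and the labels give palmitate 2 no other treatment.

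Control 2 stood apart from controls 1 and 3, with a chi-square per degree of freedom of 2.54 against their pooled counts. By the same formula, which differs from that of the library pairs in the Results, control 1 against control 3 gave 1.26. Allowing the best share of the palmitate profile (22%) left 2.39, and removing a trend on abundance left 2.27. This argues against either, mixed or swapped material or such a trend, as the whole cause. Pearson correlations of log2 CPM of control 2 were 0.954 and 0.961 with controls 1 and 3. With palmitate 1 to 3 they were 0.962, 0.953 and 0.958, so mixed material as a part of the cause is not excluded. Controls 2 and 3 have near-equal totals but a pairwise chi-square of 2.03, against 1.2 for controls 1 and 3. Unequal depth thus does not account for it either. No biological explanation was tested, and the cause stays open.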
